A study of Mus musculus with 9 samples.

How the data were processed

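RNA from 9 pieces of male mouse liver tissue was measured on 1-colour Affymetrix 3' expression arrays with 45101 probe sets each, 1 array per piece. The labels assign 3 pieces to each of 3 groups. Wild-type liver came from a wild-type mouse. Adjacent liver and tumor came from a mouse heterozygous for Sart1, which the labels write as SART1+/-. All animals were 12 months old, of the C57Bl6 strain, untreated and on regular chow. The labels describe the tumor as a hepatocellular carcinoma with severe steatosis, the adjacent liver as altered cells with severe steatosis, and the wild-type liver as normal with mild steatosis.

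The values used are the deposited log2 expression values per probe set, which the authors made with RMA in Affymetrix Expression Console 1.3.1.187, per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set. The log base was checked on the values: read as powers of 2, the brightest probe set corresponds to an intensity of 23383, within what a 16-bit scanner can record, whereas read as powers of e it would be 2009005, which is beyond it. The medians of the 3 arrays of each group were 5.81, 5.81 and 5.78 in wild-type liver, 5.78, 5.80 and 5.76 in adjacent liver, and 5.78, 5.81 and 5.80 in tumor. No 2 arrays held identical values. No detection calls were used here, so a level near the bottom of the scale cannot be told from background, and a log2 difference against such a level depends on that background. Quantile-type normalization also hides any change that moves most genes one way. The number of arrays, 3 per group, limits the precision. Scan dates and array batches are not given in the sources used here, so a batch that followed the groups would not show.

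Probe sets were named through the platform's annotation table. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none, 51 of which were control probe sets. The Entrez identifiers of 34754 probe sets with 1 symbol were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Only probe sets with 1 symbol were used. A gene with several probe sets was represented by the one with the highest mean over the 9 arrays, which concerned 9012 of 18193 genes. A gene was tested when it lay above the 40th percentile of an array on at least 3 of the 9 arrays, which left 13887 genes. Genes of near-identical families, such as the Cyp2c and Mup genes, may share signal through cross-hybridisation, and their separate values are uncertain.

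Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group and all 9 arrays in a single model (lmFit and eBayes, 6 residual degrees of freedom) and Benjamini-Hochberg adjustment over all genes tested. A gene was called when its adjusted p was under 0.05 and its log2 difference was at least 1 in size, which is 2-fold. Every adjusted p below comes from limma. Per the submitters' design description, the 3 pieces of a group came from 1 animal, and tumor and adjacent liver from the same animal. The p-values therefore measure the spread between pieces of 1 liver or tumor, not between animals, and an effect of the genotype cannot be told apart from a difference between the 2 animals. The step was tested on simulated data with the real means and spreads of the 13887 genes. Changes of 2 and 4 on the log2 scale were all called in each comparison. Of changes of 1, a 50% share was called for tumor against wild-type liver, 60% for tumor against adjacent liver and 38% for adjacent against wild-type liver. A share near 50% follows from the minimum difference of 1 that a call needs. Each share rests on 50 genes, so they do not rank the comparisons by sensitivity. At most 1 unchanged gene was called.

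Before the data were examined, 36 gene lists were fixed, covering liver functions, tumor markers, stress and hypoxia responses and markers of other cell types. Some lists share genes, such as Cyp7b1 in the P450, male-biased and bile acid lists, so lists that pass are not independent results. Each was tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 36 lists of a comparison. The comparisons, tests, alternatives and the rule for named genes were fixed at the same time. The rule takes, per comparison, the 10 called genes with the largest increase and the 10 with the largest decrease whose 3 values in each group do not overlap, up to 4 members of each list with the smallest adjusted p, and always Sart1, Ccl5, Hif1a, Epas1, Afp and Gpc3. Genes outside the rule were chosen after their values were seen and are marked so.

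Alternatives covered the threshold, the filter on dim probe sets, the rule for several probe sets, further normalization by array medians or cyclic loess, the variance model, array weights, the 2 groups of a comparison alone, a block on the replicate number, and each array left out in turn. Control probe sets were left out of the tests and used only to describe RNA quality. Probe sets with several symbols or none were tested separately and are given only as counts. No genome sequence was used here, and no coordinates are given. The RefSeq table served for gene names and for the order of genes along chromosomes.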

Results

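Sart1 encodes a component of the U4/U6.U5 tri-snRNP of the spliceosome, also known as hypoxia-associated factor, a protein that acts on the hypoxia-inducible factors Hif1a and Epas1. Male mice with 1 altered copy of Sart1 developed hepatocellular carcinoma from 10 months of age, per the sample notes. Expression was measured in 3 pieces each of wild-type liver, liver adjacent to a tumor and the tumor itself, at 12 months. The design asks how the tumor differs from normal liver and from its neighbouring liver, and how far that neighbouring liver has itself moved from normal. Arrays of the same group correlated at r = 0.996 to 0.998 across probe sets. Tumor and adjacent liver correlated at 0.983 to 0.984, wild-type and adjacent liver at 0.966 to 0.969, and wild-type liver and tumor at 0.959 to 0.962. Probe sets are not independent replicates, and these values describe the arrays.

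RNA quality probes differed somewhat between groups. The 3' minus 5' difference of Actb was 0.86 ± 0.02 in wild-type liver, 0.85 ± 0.05 in adjacent liver and 0.59 ± 0.09 in tumor (log2, SD, n = 3). That of Gapdh was 0.27 ± 0.02, 0.16 ± 0.02 and 0.21 ± 0.01 in the same order. The middle probe set of 18S ribosomal RNA was at 7.75 ± 0.73 in wild-type liver, 6.43 ± 0.22 in adjacent liver and 6.52 ± 0.02 in tumor.

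Sart1 itself was lower in tumor than in wild-type liver, at 7.74 ± 0.03 against 8.34 ± 0.02, a log2 difference of -0.60 (SE 0.05, adjusted p = 2.61e-06). In the adjacent pieces, which carry the heterozygous label, it was at 8.37 ± 0.03, a difference from wild type of 0.03 (SE 0.05, adjusted p = 0.678). Tumor against adjacent liver gave -0.63 (SE 0.05, adjusted p = 4.88e-06). Another probe set of the gene was close to background, at 5.71 ± 0.07 in wild-type liver, 5.57 ± 0.16 in adjacent liver and 5.38 ± 0.13 in tumor. A level equal to wild type does not by itself show the loss of 1 copy, so the adjacent pieces are called adjacent-labelled liver here. It does not settle their label either, because genes near Sart1 on chromosome 19 were mostly higher in these pieces. Over the 50 nearest tested genes the median difference from wild-type liver was 0.29, and 22% of them lay below Sart1. Where the probes lie relative to the altered allele is not given in the sources used here, so the Sart1 level may not test the genotype.

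**Figure D1:**
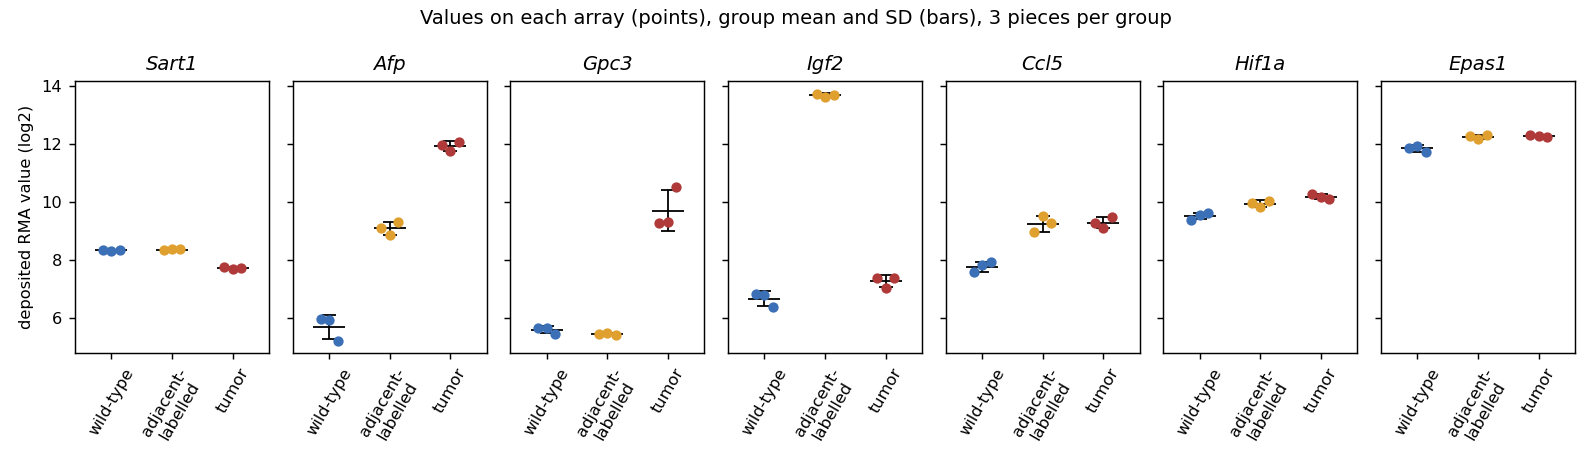
Deposited log2 values (vertical axis) of 7 genes in wild-type liver, adjacent-labelled liver and tumor; points are the 3 arrays of a group in replicate order, and bars give the group mean and SD. Sart1 is lower in tumor alone, Gpc3 is higher in tumor alone (9.70 ± 0.70), and Igf2 stands at 13.68 ± 0.06 in adjacent-labelled liver against 7.29 ± 0.20 in tumor.

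Tumor against wild-type liver asks what changed in the carcinoma. The tumor pieces expressed fetal and tumor-associated genes that were low in wild-type liver. Afp, the fetal plasma protein alpha-fetoprotein, rose by 6.21 on the log2 scale (SE 0.19), from 5.72 ± 0.42 to 11.93 ± 0.16, and Gpc3, the oncofetal proteoglycan glypican 3, rose by 4.10 (SE 0.26, n = 3 per group). The largest increases among called genes were Tspan8, a tetraspanin, at 8.04 (SE 0.09) and Cpe, the prohormone-processing enzyme carboxypeptidase E, at 7.98 (SE 0.10). They were followed by the carbonyl reductase Cbr3 at 7.36, Ly6d at 6.61, the siderophore-binding protein Lcn2 at 6.33, Ocstamp at 6.13, Rad51b at 6.11, the serine synthesis enzyme Psat1 at 5.89 and the trefoil factor Tff3 at 5.88. Wild-type values of Tspan8, Cpe, Rad51b and Psat1 lay below the 40th percentile of the arrays, so the size of those increases depends on background. Of 14 tested tumor and oncofetal markers, 11 rose and 0 fell, with a list median of 4.21. Scd2 rose by 5.53 and Golm1 by 4.53. Other, dimmer probe sets of Afp and Cpe gave -0.11 (adjusted p = 0.133) and -0.51 (adjusted p = 0.00899). The list passed camera at an adjusted p = 1.17e-07, and at an adjusted p = 0.0271 with an estimated correlation.

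The 10 largest losses in the tumor were mostly of enzymes and a transporter of liver metabolism. The log2 differences were -7.21 (SE 0.34) for the fatty acid elongase Elovl3, -7.09 (SE 0.16) for the steroid enzyme Hsd3b5, -6.95 for the sulfotransferase Sult2a8, -6.27 for the organic anion transporter Slco1a1 and -6.11 for the urinary protein gene Mup10. Among cytochrome P450 genes, Cyp2c54 changed by -6.89, Cyp2c50 by -6.27, Cyp2c37 by -6.16, Cyp4a14 by -5.93 and the bile acid enzyme Cyp8b1 by -5.81. Tumor values of Hsd3b5 and Mup10 were below the 40th percentile. Of 37 tested P450 genes, 20 fell and 2 rose (camera adjusted p = 6.39e-08; adjusted p = 0.11 with an estimated correlation). Of 14 male-biased genes, 11 fell and 0 rose (adjusted p = 1.3e-06; adjusted p = 0.185 with an estimated correlation), among them Nudt7 at -3.42 and Cyp7b1 at -4.46. Of 17 bile acid genes, 12 fell and 2 rose (adjusted p = 0.000235; adjusted p = 0.209 with an estimated correlation). Slc27a5 was at -1.96, whereas the efflux transporter Abcc4 rose by 5.04. Of 16 genes of gluconeogenesis and amino acid catabolism, 9 fell and 0 rose, which passed at an adjusted p = 6.39e-08 and at an adjusted p = 0.0261 with an estimated correlation. G6pc changed by -3.10, Tat by -2.55, Prodh by -4.21 and Pck1 by -1.73.

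Several other hepatocyte lists also passed, though not with an estimated correlation. Of 13 pericentral genes, 11 fell and 0 rose, among them Cyp27a1 at -2.48, Rgn at -4.33 and Slc1a2 at -2.95 (adjusted p = 0.000685; adjusted p = 0.422 with an estimated correlation). Of 19 general hepatocyte genes, 8 fell and 0 rose, including Bhmt at -2.11, Mat1a at -1.35 and the urea cycle enzyme Otc at -1.89 (adjusted p = 0.000235; adjusted p = 0.0588 with an estimated correlation). Of 19 genes of fatty acid synthesis, 7 fell and 1 rose, including Thrsp at -3.05, Acss2 at -2.27 and Acacb at -2.89 (adjusted p = 0.000289; adjusted p = 0.412 with an estimated correlation). Of 18 genes of fatty acid oxidation, 4 fell and 2 rose, and the list passed as lower with a median of -0.61, although Fgf21 was at 2.36. Its adjusted p in camera was 0.0175, and 0.549 with an estimated correlation. Periportal genes did not pass, with 3 higher and 3 lower of 11 (adjusted p = 0.217), nor did lipid droplet genes, with 3 higher and 6 lower of 15 (adjusted p = 0.25), although Lpl rose by 3.46.

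Lists of cell cycle and stress genes passed as higher in the tumor, although not every member was called. Of 26 cell cycle genes, 16 rose and 0 fell, with a median of 1.37, including the replication helicase subunit Mcm6 at 2.23, Nusap1 at 2.82, Ccne1 at 1.67 and Ccnb2 at 3.55 (adjusted p = 9.74e-07; adjusted p = 0.345 with an estimated correlation). Of 16 targets of the oxidative stress regulator NRF2, 10 rose and 0 fell, including Srxn1 at 3.69, Gstm3 at 1.91 and the cystine transporter Slc7a11 at 5.30 (adjusted p = 2.16e-07; adjusted p = 0.185 with an estimated correlation). Of 14 p53 targets, 8 rose and 0 fell, with Psrc1 at 5.29, Phlda3 at 2.85, Btg2 at 2.28 and Zmat3 at 1.48 (adjusted p = 3.62e-05; adjusted p = 0.11 with an estimated correlation). Of 17 genes of the unfolded protein and integrated stress responses, 6 rose and 1 fell, with Trib3 at 3.12, Atf3 at 2.19, Ddit3 at 1.36 and Herpud1 at -1.21 (adjusted p = 0.00943; adjusted p = 0.28 with an estimated correlation).

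Lists of chemokine, interferon, MHC class II and matrix genes also passed as higher against wild-type liver, although not every member was called. Ccl5, a chemokine for T cells and monocytes, rose by 1.52 (SE 0.14, adjusted p = 5.13e-06). Of 26 chemokines and cytokines, 11 rose and 1 fell, including Cxcl1 at 1.56, Tgfb1 at 1.39, Il1rn at 1.59 and Cx3cl1 at 1.26 (camera adjusted p = 0.00343; adjusted p = 0.209 with an estimated correlation). Another probe set of Tgfb1 gave 0.0079 (adjusted p = 0.927). Of 16 interferon-stimulated genes, 12 rose and 0 fell, with Oas1a at 2.70, Usp18 at 2.16 and Ifi27l2a at 2.11 (adjusted p = 9.74e-07; adjusted p = 0.209 with an estimated correlation). All 6 tested MHC class II genes rose, including H2-Ab1 at 1.91 and H2-Aa at 1.69 (adjusted p = 0.00435; adjusted p = 0.398 with an estimated correlation). A dimmer probe set of 1 of them, H2-DMa, gave -0.22 (adjusted p = 0.0333). Of 19 stellate cell and matrix genes, 13 rose and 1 fell, with Col1a1 at 2.66, Col5a2 at 2.38 and Timp1 at 1.59 (adjusted p = 0.000235; adjusted p = 0.393 with an estimated correlation).

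Markers of other cell types were mixed. Of 18 macrophage markers, 7 rose and 2 fell (adjusted p = 0.0235; adjusted p = 0.412 with an estimated correlation), with Cd68 at 1.40 and Lyz2 at 1.35 but the scavenger receptor Cd163 at -4.87. The macrophage call was lost with a filter at the 60th percentile (adjusted p = 0.0833). Neutrophil markers passed with 3 of 9 higher, S100a8 at 3.27 and S100a9 at 2.63 among them (adjusted p = 0.0361; adjusted p = 0.345 with an estimated correlation), but not without tumor replicate 3 (median 0.69, adjusted p = 0.0507). B and plasma cell markers passed with 2 of 7 higher, Jchain at 2.23 and Cd79b at 1.04 (adjusted p = 0.0266; adjusted p = 0.345 with an estimated correlation), and not under the same stricter filter (adjusted p = 0.0537). Cholangiocyte markers passed with 2 of 8 higher, Cldn7 at 3.81 and Krt23 at 2.41 (adjusted p = 0.0425; adjusted p = 0.209 with an estimated correlation). That call was lost without tumor replicate 2 or 3, wild-type replicate 3 or adjacent-labelled replicate 1 or 2, at adjusted p = 0.0507 to 0.059 and medians of 0.29 to 0.43, and with the stricter filter (adjusted p = 0.0809). T cell markers (0 of 10 called, adjusted p = 0.726), NK cell markers (1 of 8, Klrd1, adjusted p = 0.085) and endothelial markers (2 higher and 1 lower of 16, adjusted p = 0.397) did not pass.

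Hypoxia genes gave a mixed picture. Hif1a was higher in tumor by 0.66 (SE 0.08, adjusted p = 4.07e-05) and Epas1, which encodes HIF-2 alpha, by 0.43 (SE 0.07, adjusted p = 0.000287), both under the 2-fold limit. HIF-1 targets did not pass, with 5 higher and 2 lower of 22 (adjusted p = 0.344). Hk2 rose by 1.298, Aldoa by 1.13 and Pfkfb4 by 1.11, while Mxi1 was at -1.19. HIF-2-associated genes passed with 3 of 6 higher, Ccnd1 at 2.29, Mmp14 at 1.52 and Tgfa at 1.20 (adjusted p = 0.00615; adjusted p = 0.185 with an estimated correlation). Other probe sets of Tgfa gave 0.27 (adjusted p = 0.0786) and 0.16 (adjusted p = 0.0497). Adjusted over the list alone, 4 of its members were called, the only list and comparison in which that count differed from the count over all genes tested. No tri-snRNP gene was called (0 of 15, adjusted p = 0.825). Lists of cholesterol synthesis, female-biased, acute phase, Wnt target, adipose and pancreas genes did not pass, at adjusted p = 0.273, 0.33, 0.0639, 0.099, 0.698 and 0.963. Acute phase genes passed with no filter, the mean of probe sets, eBayes with trend and without wild-type replicate 3 (adjusted p = 0.0175 to 0.0431). NK cell markers passed with cyclic loess, the mean of probe sets and the most variable one (0.0306 to 0.0496), and Wnt targets without tumor replicate 1 (0.0199). The erythroid list had 1 tested gene, Alas2, at -2.70. It counts among the lists that passed (adjusted p = 0.0481; adjusted p = 0.209 with an estimated correlation). Its call was lost in several alternatives, among them no filter, the stricter filter, the most variable probe set, the 2 groups alone, ranks, and without adjacent-labelled replicate 1, 2 or 3 or tumor replicate 3 (0.0507 to 0.583). With no filter the list median was 0.15 in place of -2.70 (adjusted p = 0.583).

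In all, 1806 of 13887 genes were called between tumor and wild-type liver, 1168 higher and 638 lower, and 8798 passed the adjusted p alone. Over all genes tested, 69.1% had groups without overlap, where chance gives 10%. Camera passed 23 of the 36 lists with the preset correlation and 2 with an estimated one. Among the called genes named above, another probe set of Acss2, Afp, Aldoa, Col1a1, Col5a2, Cx3cl1, Ddit3, Mmp14, Mxi1, Slc1a2, Srxn1 and Thrsp changed the same way but by less than the 2-fold limit. These counts compare 3 pieces of 1 tumor with 3 pieces of 1 normal liver, and animal, genotype, labelled steatosis and tumor differ together.

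Adjacent-labelled against wild-type liver asks how far the tissue next to the tumor had moved. It gained about as many genes as the tumor (1152 against 1168 higher) and lost fewer (447 against 638 lower). Cpe was higher by 8.22 (SE 0.10), Apela, a peptide ligand of the apelin receptor, by 7.21 (SE 0.10), Tspan8 by 7.20, the microvillus protein Vil1 by 7.11 and Igf2, the fetal growth factor, by 6.998 (SE 0.13), which brought Igf2 from 6.68 ± 0.26 to 13.68 ± 0.06. Rragd at 6.66, the ubiquitin-like Ubd at 6.57, Anxa13 at 6.24, Cbr3 at 6.202 and Lcn2 at 6.002 completed the 10 largest increases. Wild-type values of Cpe, Apela, Tspan8, Vil1, Rragd and Ubd were below the 40th percentile. Another, dimmer probe set of Cpe gave -0.37 (adjusted p = 0.0385). Afp rose by 3.38 (SE 0.19), or by -0.0079 and 0.037 with 2 of its other probe sets (adjusted p = 0.916 and 0.84), whereas Gpc3 was at -0.15 (SE 0.26, adjusted p = 0.635). Of 14 tumor and oncofetal markers, 10 rose and 0 fell, with Scd2 at 5.46 and Golm1 at 3.84 (camera adjusted p = 8.63e-07; adjusted p = 0.0271 with an estimated correlation).

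The losses again led with male-biased and metabolic genes. Hsd3b5 changed by -6.53 (SE 0.16), Elovl3 by -6.27, Slco1a1 by -5.70, Cyp8b1 by -5.26, Cd163 by -4.98, Mup10 by -4.79, Mup3 by -4.69, the lysolipid transporter Mfsd2a by -4.41, the lipid droplet protein Cidea by -4.33 and Sult2a8 by -4.21. Of 14 male-biased genes, 9 fell and 0 rose, with Susd4 at -3.12 and Egfr at -2.12 (adjusted p = 3.21e-05; adjusted p = 0.253 with an estimated correlation). Of 37 P450 genes, 15 fell and 2 rose, with Cyp2c37 at -3.05 and Cyp26a1 at -2.71 (adjusted p = 1.41e-06; adjusted p = 0.242 with an estimated correlation). Of 16 genes of gluconeogenesis and amino acid catabolism, 10 fell and 0 rose, with Pck1 at -3.24 and G6pc at -2.80, past the test at an adjusted p = 1.62e-07 and at an adjusted p = 0.0271 with an estimated correlation. Of 19 general hepatocyte genes, 7 fell and 0 rose, with Tdo2 at -1.45, Tat at -1.75 and Arg1 at -1.02, at an adjusted p = 6.33e-06 and an adjusted p = 0.0271 with an estimated correlation. Of 13 pericentral genes, 12 fell, including Lect2 at -3.14 and Lgr5 at -1.98 (adjusted p = 7.02e-05; adjusted p = 0.40 with an estimated correlation). Of 18 genes of cholesterol synthesis, 8 fell and 0 rose, with Ebp at -1.53, Fdps at -1.81, Lss at -1.81 and Idi1 at -1.47 (adjusted p = 8.63e-07; adjusted p = 0.332 with an estimated correlation). Bile acid genes passed with 7 lower and 1 higher of 17 and fatty acid synthesis with 7 lower of 19, at adjusted p = 0.00106 and 0.00188. With an estimated correlation these were at an adjusted p = 0.287 and an adjusted p = 0.492.

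Lists of cell cycle, interferon, MHC class II, chemokine and matrix genes passed here as well, while those of immune cell markers did not. Of 26 cell cycle genes, 18 rose and 0 fell, with a median of 1.65, Mcm6 at 3.42, Ccnb2 at 3.87 and Top2a at 2.69 (adjusted p = 8.63e-08; adjusted p = 0.332 with an estimated correlation). Of 16 interferon-stimulated genes, 14 rose, with Oasl2 at 2.94, Oas1a at 2.81 and Zbp1 at 2.09 (adjusted p = 3.1e-07; adjusted p = 0.253 with an estimated correlation). Of 19 stellate cell and matrix genes, 13 rose and 1 fell, with Sparc at 2.67, Col5a2 at 2.87, Col4a1 at 2.32 and Timp1 at 2.29 (adjusted p = 7.73e-05; adjusted p = 0.40 with an estimated correlation). A dimmer probe set of Sparc gave -0.25 (adjusted p = 0.00747). Of 6 MHC class II genes, 5 rose, with Cd74 and H2-Ab1 both at 2.05 (adjusted p = 0.00375; adjusted p = 0.40 with an estimated correlation). Ccl5 rose by 1.48 (SE 0.14), and 12 of 26 chemokines and cytokines rose, including Il1rn at 2.12 and Cxcl14 at 1.749 (adjusted p = 0.00106; adjusted p = 0.253 with an estimated correlation). Of 16 NRF2 targets, 7 rose, with Gpx2 at 2.92 and Gstm3 at 2.29 (adjusted p = 7.68e-06; adjusted p = 0.253 with an estimated correlation).

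Wnt and beta-catenin targets passed with 6 lower and 1 higher of 11, the higher one being Ccnd1 at 2.57 (adjusted p = 0.0228; adjusted p = 0.465 with an estimated correlation). Axin2, Lgr5, Glul, Lect2 and Tbx3 are on both this list and the pericentral one. HIF-2-associated genes passed with 2 of 6 higher, Ccnd1 and Mmp14 (adjusted p = 0.0185; adjusted p = 0.253 with an estimated correlation). Acute phase genes passed with 5 higher and 1 lower of 18, Apcs at 1.305 and Steap4 at 1.23 among them (adjusted p = 0.0394; adjusted p = 0.40 with an estimated correlation). Their call was lost without adjacent-labelled replicate 2 (median 0.36, adjusted p = 0.0564), with the stricter filter (adjusted p = 0.103), with cyclic loess (0.0749) and on ranks (0.0593). HIF-1 targets (2 higher and 1 lower of 22, adjusted p = 0.75) and p53 targets (1 higher and 1 lower of 14, adjusted p = 0.502) did not pass. Hif1a differed by 0.43 (SE 0.08, adjusted p = 0.00102), or by 0.031 with another probe set (adjusted p = 0.791), and Epas1 by 0.40 (SE 0.07, adjusted p = 0.000489). Macrophage, neutrophil, NK cell, B cell, T cell, endothelial and cholangiocyte markers were at adjusted p = 0.0545, 0.0609, 0.079, 0.566, 0.566, 0.176 and 0.122. Macrophage markers passed in several alternatives (adjusted p = 0.0109 to 0.0494), among them no filter, the mean of probe sets, the 2 groups alone, ranks, and without wild-type replicate 1, 2 or 3, adjacent-labelled replicate 2 or tumor replicate 2 or 3. Neutrophil markers passed with no filter, with cyclic loess and without wild-type replicate 1 (adjusted p = 0.0164 to 0.0481). NK cell markers passed with cyclic loess and with the most variable probe set (adjusted p = 0.0339 and 0.0375), and cholangiocyte markers with no filter (0.0437). Lists of periportal, lipid droplet, fatty acid oxidation, unfolded protein response, female-biased, tri-snRNP, pancreas and adipose genes were at adjusted p = 0.54, 0.371, 0.122, 0.392, 0.75, 0.464, 0.75 and 0.392. Alas2, the tested erythroid gene, was at -2.32 (adjusted p of the list 0.0531), and its list passed in 6 alternatives (0.0449 to 0.0494). These were arrays shifted to one median, cyclic loess, eBayes with trend, and without wild-type replicate 1 or 2 or tumor replicate 2.

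This comparison called 1599 genes, 1152 higher and 447 lower, and 8744 passed the adjusted p alone. Groups did not overlap in 69.5% of genes, where chance gives 10%. Camera passed 18 lists with the preset correlation and 3 with an estimated one. Another probe set of Egfr, Lss, Mmp14 and Tspan8 changed the same way but by less than the 2-fold limit. Genotype, animal and the labelled degree of steatosis cannot be told apart in it.

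Many calls against wild-type liver coincided between tumor and adjacent-labelled liver. Of the genes tested, 771 were higher in both, where independent lists would share 96.9, and 321 were lower in both, where independent lists would share 20.5. Among them were Cpe, Tspan8, Cbr3, Lcn2 and Afp on the higher side and Hsd3b5, Elovl3, Slco1a1, Cyp8b1 and Cd163 on the lower side. In 20 simulations of unchanged groups against the same wild-type arrays, limma called 0 genes in both, which is chance with no effect and does not measure what shared arrays add to lists of changed genes. The 3 wild-type arrays are too few to give each comparison at least 2 of its own, so part of the excess may come from the shared arrays. Per the submitters' design, all wild-type pieces came from the same animal, and all tumor and adjacent-labelled pieces from another. A feature of either animal, or the severe steatosis in the labels of both tissues, would enter both comparisons. Separate arrays of the same wild-type animal would not remove this. Of the 771 genes, 682 were not called between tumor and adjacent-labelled liver, 46 were called higher in tumor and 43 higher in adjacent-labelled liver. Of the 321 genes, 263 were not called between them, 47 were called lower in tumor and 11 lower in adjacent-labelled liver.

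**Figure D2:**
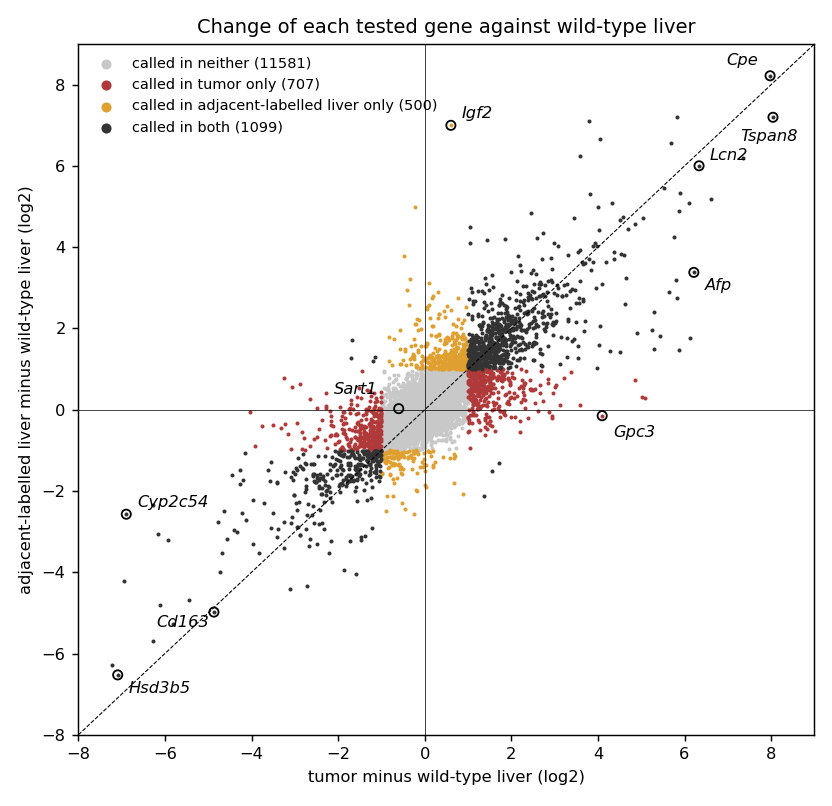
Log2 difference from wild-type liver of each of 13887 tested genes in tumor (horizontal axis) and in adjacent-labelled liver (vertical axis), coloured by whether the gene was called in neither, one or both comparisons; the dashed line marks equal change. Igf2 lies far above the dashed line (6.998 against 0.60) and Gpc3 far below it (-0.15 against 4.10).

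Tumor against adjacent-labelled liver compares tissue from a single mouse, per the submitters' design, and asks what marks the carcinoma off from its surroundings. The sharpest difference was Igf2, at -6.39 (SE 0.13), from 13.68 ± 0.06 in adjacent-labelled liver to 7.29 ± 0.20 in tumor. Higher in tumor were the chemokine Cxcl3 at 4.79 (SE 0.20), the activin antagonist Fst at 4.70 (SE 0.10), the cadherin Cdh17 at 4.41, Ocstamp at 4.37, Gpc3 at 4.25 (SE 0.26), Galnt6 at 4.12, Psrc1 at 3.79, Csn3 at 3.62, Hsd17b6 at 3.51 and the arginase Arg2 at 3.48. Afp differed by 2.83 (SE 0.19), or by -0.10 (adjusted p = 0.20) and 0.64 with 2 of its other probe sets. Lower in tumor were Eci3 at -5.20, Cyp2c54 at -4.32, the prostaglandin D synthase Ptgds at -4.26, Acnat2 at -4.02, Cyp2c23 at -3.98, Cyp2c50 at -3.93, 9130409I23Rik at -3.62, Sdr16c5 at -3.56 and Tenm3 at -3.51. Cxcl3 and Arg2 in adjacent-labelled liver, and Eci3, Acnat2, Sdr16c5 and Tenm3 in tumor, were below the 40th percentile.

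Of 6 lists that passed camera here, 4 were higher and 2 lower in tumor, and all were lost with an estimated correlation. Of 14 p53 targets, 8 rose and 0 fell, with a median of 1.11, Phlda3 at 2.20, Btg2 at 1.63 and the p53 ubiquitin ligase Mdm2 at 1.35 (adjusted p = 1.51e-08; adjusted p = 0.12 with an estimated correlation). Of 18 genes of cholesterol synthesis, 5 were higher and 0 lower, with Lss at 2.49, Nsdhl at 1.36 and Dhcr7 at 1.02. In camera the list was at an adjusted p = 1.2e-07, and at an adjusted p = 0.674 with an estimated correlation. Against wild-type liver, the list median was -0.11 in tumor and -0.83 in adjacent-labelled liver, so the difference lay mostly in lower values of the latter. Of 17 genes of the unfolded protein and integrated stress responses, 5 rose and 0 fell, with Trib3 at 1.99, Creld2 at 1.79, Manf at 1.59 and the chaperone Hsp90b1 at 1.12 (adjusted p = 3.6e-05; adjusted p = 0.426 with an estimated correlation). B and plasma cell markers passed with 1 of 7 called, the antibody joining chain Jchain at 2.04 (adjusted p = 0.0226; adjusted p = 0.674 with an estimated correlation). Of 37 P450 genes, 14 fell and 3 rose, with Cyp4f14 at -3.14 and Cyp2c37 at -3.11 (adjusted p = 0.00152; adjusted p = 0.674 with an estimated correlation). Of 17 bile acid genes, 6 fell and 0 rose, with Cyp7b1 at -2.86, Baat at -1.31 and Abcb11 at -1.24 (adjusted p = 0.0226; adjusted p = 0.77 with an estimated correlation). The B cell and bile acid calls were lost with the 60th percentile filter (adjusted p = 0.0845 and 0.0746).

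Several genes that separated both tissues from wild type separated them little or not at all from each other. Ccl5 differed by 0.04 (SE 0.14, adjusted p = 0.845) and Epas1 by 0.03 (SE 0.07, adjusted p = 0.788). Epas1 did separate them with the more variable of its probe sets (0.42, adjusted p = 0.00506) and with the mean of its probe sets (0.23, adjusted p = 0.0229). Hif1a differed by 0.23 (SE 0.08, adjusted p = 0.038), which did not hold in several alternatives, among them when adjacent-labelled replicate 1 or 2, tumor replicate 1 or 2 or wild-type replicate 2 was left out (differences of 0.17 to 0.25), or with arrays shifted to one median (adjusted p = 0.073). Cell cycle genes did not pass (0 higher and 1 lower of 26, adjusted p = 0.201), with Mcm6 at -1.19, but they passed without adjacent-labelled replicate 2 (median -0.43 against -0.29, adjusted p = 0.00115). Oncofetal markers had 3 higher and 1 lower of 14, Ly6d at 1.42 among the former (adjusted p = 0.181). HIF-1 targets had 1 of 22 called, the prolyl hydroxylase Egln3 at 1.98 (adjusted p = 0.187). NRF2 targets had 3 higher and 1 lower of 16, with Slc7a11 at 2.89, Srxn1 at 1.498 and Gpx2 at -1.60 (adjusted p = 0.0591). That list passed with no filter, with arrays shifted to one median, and without adjacent-labelled replicate 1 or 2 or tumor replicate 1 (adjusted p = 0.0301 to 0.0484). Interferon-stimulated genes had 1 lower of 16, Oasl2 at -1.45 (adjusted p = 0.431). Matrix genes had 2 lower of 19, Sparc at -1.56 (0.12 with its dimmer probe set) and Col4a1 at -1.08 (adjusted p = 0.348).

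The other lists did not pass either. Chemokine, macrophage, T cell, NK cell, neutrophil, endothelial, cholangiocyte and MHC class II genes were at adjusted p = 0.563, 0.592, 0.816, 0.922, 0.584, 0.657, 0.869 and 0.867. General hepatocyte, pericentral, periportal, male-biased and female-biased genes were at adjusted p = 0.816, 0.816, 0.816, 0.181 and 0.584, although Pck1 was at 1.51, Cyp1a2 at 1.32, Susd4 at 1.73 and Bhmt at -1.72. Without adjacent-labelled replicate 2, male-biased genes and fatty acid oxidation passed (adjusted p = 0.0442 and 0.0304). Lists of fatty acid synthesis, lipid droplet, fatty acid oxidation, gluconeogenesis, acute phase, Wnt target, HIF-2-associated, tri-snRNP, pancreas and adipose genes were at adjusted p = 0.523, 0.584, 0.181, 0.59, 0.657, 0.506, 0.563, 0.657, 0.80 and 0.844. Alas2 was at -0.38.

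Between tumor and adjacent-labelled liver, 700 genes were called, 292 higher and 408 lower, and 6274 passed the adjusted p alone. Another probe set of Col4a1, Hsp90b1, Lss and Srxn1 changed the same way but by less than the 2-fold limit. Groups did not overlap in 53.01% of genes, where chance gives 10%. Median, mean and camera direction of a list differed in sign in 5 lists here, in 2 for tumor against wild-type liver and in 4 for adjacent-labelled against wild-type liver, 0 of which passed the test.

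**Figure D3:**
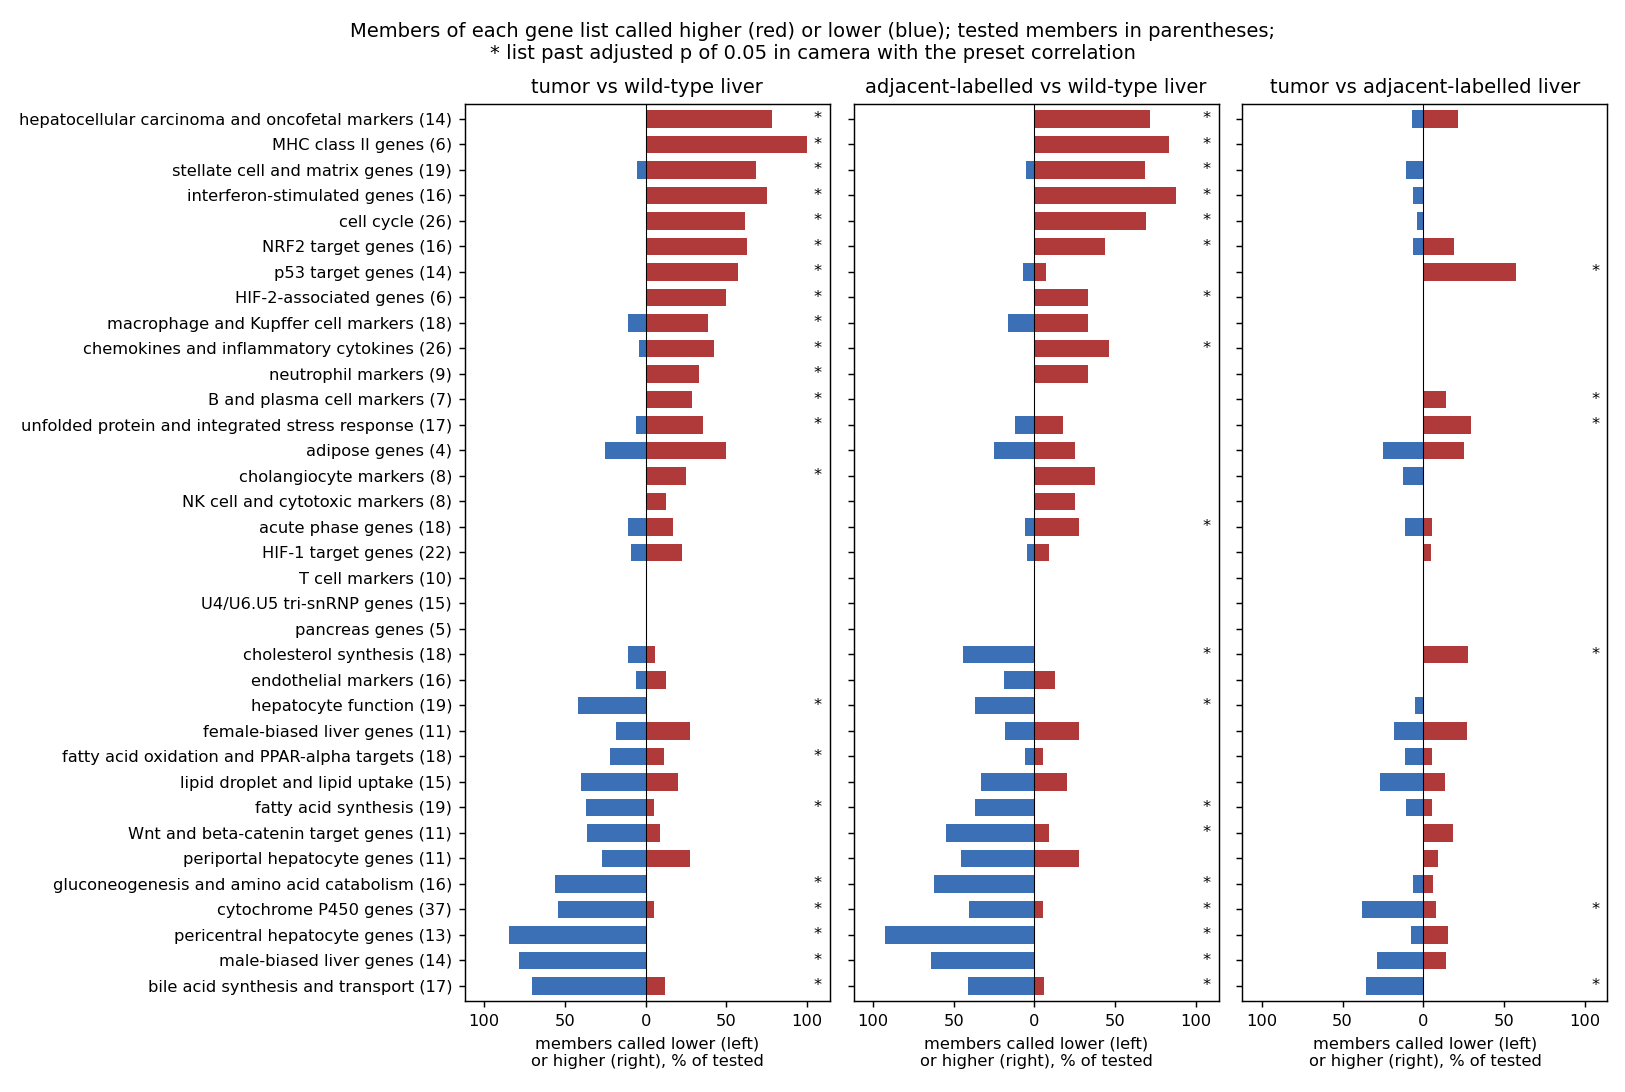
Share of each gene list's tested members (horizontal axis, % of the number in parentheses) called higher (red, to the right) or lower (blue, to the left) in the 3 comparisons, ordered by list median in tumor against wild-type liver; asterisks mark lists past an adjusted p of 0.05 in camera with the preset correlation. Against wild-type liver, 8 of 14 p53 targets were called higher in tumor and 1 of 14 in adjacent-labelled liver, and 2 and 8 of 18 genes of cholesterol synthesis were called lower. Between tumor and adjacent-labelled liver 0 lists passed with an estimated correlation (p53 targets at an adjusted p = 0.12, cholesterol synthesis at an adjusted p = 0.674).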

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

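The tests of arrays split in other ways, mixed tissue, cell loss and Sart1 were set out after the results were seen, whereas the differences between tumor and adjacent-labelled liver were planned.

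Between tumor and adjacent-labelled liver, the change from wild type itself was tested as the direct difference of the groups. Called in opposite directions against wild-type liver were 7 genes. Each was also called between tumor and adjacent-labelled liver, which their selection makes almost certain, so it is no further support. Cidec, which encodes a lipid droplet protein, was at 1.55 in tumor and -1.51 in adjacent-labelled liver (log2, n = 3 per group), Cyp2b9 at 1.72 and -1.31, and Hsd17b6 at 1.38 and -2.13. The reverse held for Acot3 at -1.20 and 1.191, Adam11 at -1.16 and 1.298, Cyp2c55 at -1.71 and 1.28 and Slc3a1 at -1.69 and 1.70. Differences between the tissues were 3.06, 3.03, 3.51, -2.39, -2.45, -2.99 and -3.39 in that order. Adam11, Cyp2c55 and Slc3a1 lie outside the rule for named genes and were chosen after their values were seen.

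The same difference passed camera for 6 lists, by their medians 1.11 for p53 targets, 0.83 for the unfolded protein and integrated stress responses, 0.67 for cholesterol synthesis, 0.45 for B and plasma cell markers, -0.55 for bile acid genes and -0.73 for P450 genes. With an estimated correlation none of the 6 passed. Among 3880 tested probe sets with several gene symbols or none, 342 were called for tumor against wild-type liver, 132 for tumor against adjacent-labelled liver and 287 for adjacent-labelled against wild-type liver. These probe sets are not named here. Groups of 3 arrays were not tested for single outlying arrays.

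In tumor against wild-type liver, 1 of the 10 splits of the 6 arrays, the real one, gave as many calls (1806, highest other 0). In tumor against adjacent-labelled liver it was again 1 of 10 (700, highest other 1), and in adjacent-labelled against wild-type liver 1 of 10 (1599, highest other 0). With 10 splits a share under 0.05 cannot be reached.

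Tumor-type genes were high in adjacent-labelled liver, and tumor tissue mixed into those pieces may account for part of this. Such a mixture as the whole cause is argued against by the genes beyond the tumor level, which were 13.8% of the 1599 genes called there (221 genes), where error alone gave at most 0.125% in 200 draws. The share of tumor needed also differed between genes, with quartiles of 37.8% and 115%. It was under 10% for 122 of the 1168 genes higher in tumor, and -0.6% for Gpc3. These 122 genes were picked by their low share and without an allowance for error, so they set no limit on the share of tumor. The stellate list median exceeded the endothelial one by 2.10 (95% interval 1.16 to 2.93), so these lists did not rise alike. Whether hepatocytes were lost cannot be decided from this, because the listed genes may also change within cells. The interval resamples genes and ignores the correlation between them. Open and untested remain a separate lesion in these pieces, genotype, steatosis and a difference between the animals.

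Sart1 stood at the wild-type level in adjacent-labelled liver, at a difference of 0.026, and whether these pieces came from a mouse without the Sart1 change cannot be told apart, because the position of the probes on the altered allele is not given in the sources used here. Genes around Sart1 may be higher as a group in adjacent-labelled liver than in tumor: of the 50 nearest tested genes, 24% lay below Sart1 in tumor minus adjacent-labelled liver. Their median was -0.43 against -0.63 for Sart1. That test allows a wide range and decides little. Against wild-type liver, 8% of these genes lay below Sart1 in tumor and 22% in adjacent-labelled liver. In adjacent-labelled against wild-type liver their median was 0.29, and that of the other tested genes on chromosome 19 was 0.27. Such a rise of the region may hide a lower Sart1 level, which was not tested.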

How the results depend on the processing

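No alternative was chosen after the results were seen. Leaving out each array in turn kept all 8 counts within 1.5 times, at 1120 to 1194 higher and 609 to 663 lower for tumor against wild-type liver, 270 to 301 and 365 to 431 for tumor against adjacent-labelled liver, 1099 to 1177 and 421 to 482 for adjacent-labelled against wild-type liver, and 751 to 789 and 301 to 332 in both. Of 184 recomputed counts, 161 stayed within 1.5 times and 23 moved. With every probe set by itself, which counts a gene more than once, there were 1883 higher and 1018 lower in tumor against wild-type liver, 544 higher in tumor against adjacent-labelled liver, 1802 and 776 in adjacent-labelled against wild-type liver, and 1208 and 523 in both. With the adjusted p alone the counts were 4606 and 4192, 2794 and 3480, 4728 and 4016, and 3387 and 2758 in that order of comparisons. With a 1.5-fold minimum they were 2296 and 1431, 837 and 1171, 2296 and 1093, and 1582 and 760. These are looser thresholds, which pass more genes by construction.

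Among named genes, 8789 recomputed values kept their side of an adjusted p of 0.05, 86 moved above it and 46 moved below it. Another 17 reversed direction with an adjusted p under 0.05 in the main or the recomputed fit. A change of sign with both adjusted p above 0.05 counts among the 8789. These counts go by the adjusted p alone, without the minimum difference. All 17 reversals came from another, dimmer probe set of the gene, and the cause was not tested. Those without a p here had an adjusted p above 0.05. For tumor against wild-type liver these were Afp at -0.11, Cpe at -0.51 (adjusted p = 0.00899), Eftud2 at -0.11, Fabp4 at -0.0066 and H2-DMa at -0.22 (0.0333). For tumor against adjacent-labelled liver they were Afp at -0.10, Ccnd1 at 0.10, Ddx58 at 0.13 and Sparc at 0.12. For adjacent-labelled against wild-type liver they were Afp at -0.0079, Car3 at 0.0298 and 0.33, Cpe at -0.37 (adjusted p = 0.0385), Csf1 at -0.058, Eftud2 at -0.0703, Sparc at -0.25 (0.00747) and Srxn1 at -0.0802. Of the list results, 2162 stayed on their side of an adjusted p of 0.05, 67 lost and 39 gained the call. Array signal near background limits dim genes.

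With a replicate block, 1169 genes were higher and 638 lower in tumor against wild-type liver, and all 8 counts stayed within 1.5 times. By the adjusted p alone, the block put above 0.05 the Hif1a difference between tumor and adjacent-labelled liver (0.23, adjusted p = 0.0602) and the erythroid list in tumor against wild-type liver (0.0597). It put below 0.05 the macrophage list in adjacent-labelled against wild-type liver (0.0447), and Gpnmb (0.87, adjusted p = 0.0379), S100a8 (0.45, 0.00797) and Timd4 (0.48, 0.0189) between tumor and adjacent-labelled liver. It changed no other list or named gene in this way. Residuals of arrays with the same number correlated at -0.11 to 0.14 (9 pairs) and of other arrays at -0.17 to 0.15 (18 pairs). Only adjacent-labelled liver and tumor share an animal, per the submitters' design. Between these, the same numbers gave 0.09, 0.06 and 0.04, and other numbers gave -0.17 to 0.10. With 3 arrays per group these values cannot decide whether the numbers pair the pieces.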

Other observations

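The chromosome tests below were all chosen after the results were seen, and so were, in the next paragraph, Vsig4 and Clec4f, and Timd4 and Marco against wild-type liver, which lie there outside the rule for named genes.

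The macrophage scavenger receptor Cd163 fell by 4.87 in tumor (SE 0.13) and by 4.98 in adjacent-labelled liver against wild-type liver, to values below the 40th percentile. Of the 18 tested macrophage markers, 7 were called higher and 2 lower in tumor, and 6 higher and 3 lower in adjacent-labelled liver. Timd4 also fell (-1.04 in tumor and -1.52 in adjacent-labelled liver), and Marco fell in adjacent-labelled liver (-1.11). Vsig4 differed by 0.50 in tumor (SE 0.23, limma adjusted p = 0.0804) and 0.18 in adjacent-labelled liver (adjusted p = 0.508), and Clec4f by -0.057 (SE 0.28, adjusted p = 0.872) and -0.24 (adjusted p = 0.473), with 3 arrays per group.

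Some whole chromosomes differed in their median change from the rest of the genome. Listed are those beyond the limit of shuffled blocks of 25 genes, a test described below. Against wild-type liver, adjacent-labelled liver was higher on chromosomes 1 (0.29), 18 (0.28), 19 (0.27), 15 (0.22), 17 (0.22) and 5 (0.14) and lower on 10 (-0.18), 12 (-0.15) and 6 (-0.13). Tumor was higher on chromosomes 15 (0.28) and 17 (0.10) and lower on 8 (-0.18), 6 (-0.11), 19 (-0.10), 13 (-0.10) and 3 (-0.09). Tumor minus adjacent-labelled liver was lower on chromosomes 8 (-0.34), 19 (-0.33), 18 (-0.19), 1 (-0.13) and 5 (-0.09) and higher on 10 (0.26), 12 (0.16) and 9 (0.09).

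The first test was a permutation test that rotated the whole gene order, and it missed the threshold, at p = 0.062 for tumor against wild-type liver, 0.116 for tumor against adjacent-labelled liver and 0.133 for adjacent-labelled against wild-type liver, with 0 chromosomes beyond its limit. Rotation leaves chromosome-sized runs intact, and 2 other tests were chosen after it. A permutation test with shuffled blocks of 25 genes gave p = 1e-04 in each comparison, the smallest that 10000 draws can give, with 7, 8 and 9 chromosomes beyond the limit in the same order. With blocks of 50 genes it was 3, 6 and 6 chromosomes. This left out chromosomes 17, 19, 13 and 3 for tumor against wild-type liver and 5 and 9 for tumor against adjacent-labelled liver. For adjacent-labelled against wild-type liver it left out 5, 12 and 6. Gene medians on either side of the midpoint of 20 chromosomes correlated at r = 0.85, 0.93 and 0.90, with a largest p over the comparisons of 4e-04 by rank.

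Shifts in copy number may underlie this pattern, as a hypothesis that no DNA data were used to test. Among the 11459 genes called in no comparison, 24 of 24 shifts kept over 50% of their size, which decides nothing about a few strongly changed genes, since these hardly move a median and the genes were chosen by their change. A trend with expression level is argued against by 24 of 24 that kept it after that trend was removed, and runs of up to 50 neighbouring genes by the correlation across the midpoint (largest p 0.0004). A difference between the animals remains open for the 2 comparisons with wild-type liver. It is argued against for tumor minus adjacent-labelled liver, where chromosome 8 was at -0.34, since both tissues came from the same animal per the submitters' design. An array batch remains open throughout.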
